A study of Triticum aestivum with 6 samples.

How the data were processed

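RNA was extracted from about 100 mg of wheat root per replicate, enriched for polyadenylated RNA, fragmented to about 300 bp and sequenced on an Illumina instrument with reads of 150 bp on average, per the labels' protocols. Plants were grown outdoors, 15 per pot, in a steam-sterilised mixture of soil and quartz sand. There were 3 NM and 3 MSC libraries, 1 per biological replicate, and the labels name no batch.

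The authors deposited 1 table for the series, with an identifier, an FPKM value for NM and an FPKM value for MSC (headed MF, the column name that the MSC samples' descriptions give). FPKM is the number of fragments scaled by transcript length and by the number of mapped fragments of the library. The submitters' processing notes name TopHat2, Cufflinks and RSEM (version 1.3.0), without roles. The genome build, annotation, normalization beyond FPKM, the statistical test and the thresholds by which genes were chosen are not given in the sources used here. Apart from the value 0.001, all 4999 deposited FPKM values are whole multiples of 1/300 within 0.01 of a step, as the mean of 3 values with 2 decimals would be. The smallest value above 0.001 is 0.00333 FPKM, so 0.001 was treated as the authors' stand-in for a mean of 0. Rounding and averaging leave no read counts or depths to recover, and no count test was run. All 2578 items differ by at least 2.00-fold and 0 lie below 2-fold, so the table is a selection, and it cannot show how unlisted genes behaved or how the libraries were scaled against each other.

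Rows of the table follow the order of the identifiers except for 21 rows, which stand in one another's places. Whether their values moved with their identifiers is open. They were kept as deposited (18 higher, 3 lower), and results were recomputed without them. The identifiers printed in the results are not among them, but 2 of the 10 largest increases are. Altogether 90 identifiers, in 43 sets, have the same pair of values as another identifier. In 21 cases identifiers share the 9-character code after the chromosome arm, 3 of them across chromosomes, and in all 21 the values are identical. Values of such near-identical copies cannot be told apart.

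Direction was taken from the 2 group values. Changes are given as the ratio of the deposited values and as log2((MSC + 1)/(NM + 1)), a pseudocount of 1 FPKM, which understates changes of low genes. Chromosome, arm and subgenome were read from the text of the identifiers, in place of the annotation that had been planned on, because no annotation of the authors' build was used. Identifiers of 2083 items name a chromosome and 1916 of these an arm. The reference table for this work (assembly IWGSC CS RefSeq v2.1) matched 0 of the identifiers, so 28 lists of gene functions that had been fixed by keywords before the data were examined could not be applied, and neither their direction nor their over-representation was tested. The rule for single genes, also fixed before the data were examined, was the 10 largest changes in each direction with at least 5 FPKM in the higher group, with at most 2 identifiers printed per direction where none has a name. Its parts on gene lists and symbiosis markers named no gene.

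Shares have 95% Wilson intervals. Two-sided Fisher's exact tests compared shares of higher genes between classes of items. Permutation tests with 100000 resamples reassigned direction (or subgenome) over items, and a difference in medians was tested in the same way. Adjusted p-values are by Benjamini-Hochberg within each family, with a threshold of 0.05. The adjustment does not cover the choice of comparisons, such as the cut at 100 FPKM, assembled loci, homoeologous groups, arms or subgenome mix. These tests run across genes of a selected table. They say how the listed genes are distributed and not whether the treatments differ beyond the spread of root samples. Directions were simulated independently for the 2083 items. The permutation test over homoeologous groups then gave p under 0.05 in 7.0% of 200 simulations with no effect. With group 2 raised by 10 percentage points, it did so in 99.5%. That rise is larger than the difference seen in group 2 (85.5% against 79.2% in the other groups). Since simulated genes were independent, neither result covers genes that change together. Alternatives were other pseudocounts, filters on level and on fold, rescaling to equal upper quartiles, counting identical copies once and leaving out the rows out of order. Analyses used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.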

Results

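The study asked whether signal molecules that pass through soil between an arbuscular mycorrhizal fungus and wheat roots change root transcripts when the fungus and the root cannot touch. Roots of hexaploid bread wheat (Triticum aestivum, cultivar Chinese Spring, the reference cultivar of wheat genetics) were compared between 2 treatments with 3 biological replicates each. In the signal treatment (MSC), each pot held 15 bags of 0.25 µm membrane filled with 25 g of inoculum of the mycorrhizal fungus Rhizophagus irregularis, so that dissolved signals but not hyphae or spores could cross. In the non-mycorrhizal control (NM), the 15 bags held 20 g of steam-sterilised inoculum to which a filtrate of live inoculum had been returned. Messenger RNA from the roots was sequenced. The deposited table lists 2578 genes and loci with 1 FPKM value for NM and 1 for MSC. It holds no value per replicate, so no replicate spread, standard error or p-value can be attached to any gene, and the depth of the libraries is unknown. Every listed gene differed between the groups, with a smallest ratio of 2.00-fold, so that genes changed less than this were not analysed here.

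Most listed genes had the larger value in roots of the MSC treatment. Of the 2578, 2056 were higher in MSC and 522 were lower, a share of higher genes of 79.8% with a 95% Wilson interval from 78.2% to 81.3%. Among the higher genes the median went from 1.37 FPKM in NM to 5.20 FPKM in MSC. Among the lower genes the median went from 5.71 FPKM in NM to 2.06 FPKM in MSC. Leaving out genes at the lowest listed value, the median ratio was 3.21-fold for the 1927 higher genes, with quartiles of 1.28 and 2.54 on the log2 scale. It was 2.51-fold in the other direction for the 494 lower genes, with log2 quartiles of -1.75 and -1.13. The intervals on shares cover counting of genes only and not the spread between root samples. When the groups were rescaled to equal upper quartiles of the listed genes, 845 of the listed genes were at least 2-fold higher and all 522 lower genes were still at least 2-fold lower, 61.8% higher among these. The shift of -1.06 in log2 ratio can only enlarge the listed decreases, and unlisted genes that it would carry past 2-fold are not in the table, so 61.8% is not the share that a rescaled full data set would give. The shift was also computed from the listed genes themselves, most of which were higher in MSC.

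**Figure D1:**
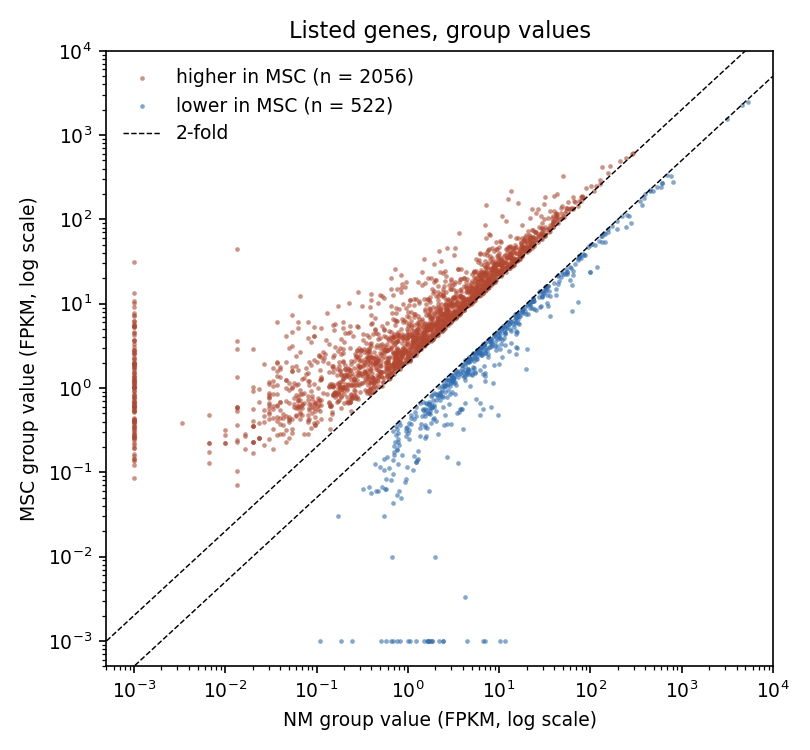
Group values of the 2578 listed genes in NM (x axis, FPKM, log scale) and MSC (y axis, FPKM, log scale), with 1 point per gene and dashed lines at 2-fold. The 2056 genes higher in MSC lie above the upper line, the 522 lower genes lie below the lower line, and points at 0.001 FPKM are genes listed at the lowest value in 1 group.

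The files do not pair identifiers with gene names, and none of the identifiers matched the reference table, so single genes are given by identifier and only for the largest changes. The gene with the largest increase on the log2(FPKM + 1) scale was Traes_2AS_E08BF60FE, whose identifier places it on the short arm of chromosome 2A. It had 0.0133 FPKM in NM and 44.9 FPKM in MSC, a log2(FPKM + 1) difference of 5.50. Traes_2BS_D105CA0D2, on the short arm of chromosome 2B, was listed at the lowest value of 0.001 FPKM in NM and at 31.2 FPKM in MSC. The largest decrease was that of Traes_6DL_4AF1E2B10, on the long arm of chromosome 6D, which had 11.6 FPKM in NM and was listed at 0.001 FPKM in MSC. It was followed by XLOC_052223, an assembled locus with no chromosome in its identifier, with 10.2 FPKM in NM and 0.001 FPKM in MSC. The 10 largest increases spanned 3.67 to 5.50 on the log2(FPKM + 1) scale, and 5 of these genes carried an identifier of chromosomes 2A, 2B or 2D. The 10 largest decreases spanned -3.66 to -2.44, and 0 of them did. Among all listed genes, these chromosomes held 414 of the 2056 higher and 70 of the 522 lower genes. Of the 10 increases 2, and of the 10 decreases 4, were listed at 0.001 FPKM in 1 group. Of the 10 decreases, 5 were assembled loci, against 2 of the 10 increases.

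A set of genes was listed in 1 treatment at the lowest value, 0.001 FPKM. There were 129 such genes in NM, which had a median of 1.02 FPKM and a maximum of 31.2 FPKM in MSC. There were 28 in MSC, with a median of 1.64 FPKM and a maximum of 11.6 FPKM in NM. These genes made up 6.27% of the higher and 5.36% of the lower genes, shares that did not differ past the threshold (two-sided Fisher's exact test across genes, p = 0.475, Benjamini-Hochberg adjusted p = 0.475 over 5 tests). This depended on the limit: with values under 0.1 FPKM in the lower group, the shares were 16.3% of the higher and 9.77% of the lower genes (336 and 51 genes, two-sided Fisher's exact test across genes, unadjusted p = 0.00012). No fold is given for the genes listed at 0.001 FPKM, since the value does not distinguish an absent transcript from one under the rounding limit. They are left out of the classes by fold of the deposited values. They stay in the class by log2(FPKM + 1) ratio and in the rescaled counts at 2-fold or more.

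The most abundant listed transcripts were split more evenly than the rest. Among 107 genes of at least 100 FPKM in their higher group, 67 were higher and 40 lower in MSC, a share of 62.6%. Below that level the share was 80.5% (two-sided Fisher's exact test across genes, adjusted p = 5.9e-05). The 3 listed genes above 1000 FPKM in NM, with 3115 to 5329 FPKM, were all lower in MSC, at 1542 to 2446 FPKM, a ratio of 2.01- to 2.18-fold. The 10 most abundant listed genes in NM were all lower in MSC, while the 10 most abundant in MSC comprised 7 higher and 3 lower genes, rankings that each favour the genes with the larger value in that group. Summed over the table, the higher genes went from 12674 FPKM to 36433 FPKM and the lower genes from 29746 FPKM to 13309 FPKM. The lower genes had a higher NM level, with a difference in median log2(FPKM + 1) of -1.50 for higher minus lower genes (permutation test, p = 1e-05, the smallest its permutations can give). This difference is partly built in, because lower genes are those with the larger NM value. With the mean of both groups it was -0.19 (permutation test, p = 0.106), which did not pass the threshold.

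In the deposited values, large changes were more often increases. Leaving out the genes listed at 0.001 FPKM in 1 group, 832 genes had a ratio of at least 4-fold, and 736 of them were higher in MSC, a share of 88.5%, against 74.95% of the genes between 2- and 4-fold (two-sided Fisher's exact test across genes, adjusted p = 3.2e-15). Among genes with at least 5 FPKM in the higher group the shares were 89.9% and 76.3% (Fisher's exact test, adjusted p = 1.4e-06). At 8-fold or more, 332 genes were higher and 29 lower, a share of 92.0%. With the groups rescaled to equal upper quartiles of the listed genes these were 158 and 100, a share of 61.2%. At 4-fold or more the rescaled counts were 314 higher and 494 lower, a share of 38.9%. All listed decreases then pass by construction, and at this shift unlisted decreases just under 2-fold could only lower this share. The shift was computed from the listed genes themselves, most of which were higher in MSC, so it works against the increases. These counts therefore do not show which direction a full data set would favour. As deposited, at 16-fold or more, 167 genes were higher and 9 lower. The classes by fold still hold genes with values near 0 in the lower group, and the limit of 5 FPKM was applied only at 4-fold. With genes at 0.001 FPKM included, 16.3% of the higher and 9.77% of the lower genes had under 0.1 FPKM in their lower group. How much such low values add to the share at 8-fold and above was not tested. All of these tests describe the listed genes, which are not replicates of the treatment.

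**Figure D2:**
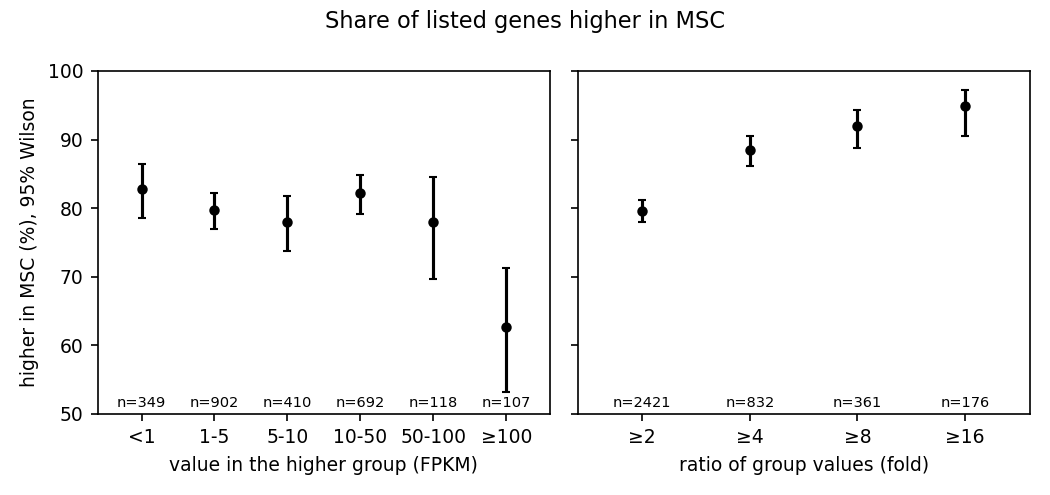
Share of listed genes higher in MSC (y axis, percent, drawn from 50 to 100) by the value in the higher group (left, FPKM) and by the minimum ratio of the group values (right, fold, each class containing the next, without genes listed at 0.001 FPKM in 1 group), with points for the share, bars for the 95% Wilson interval and n for the number of genes. The share was 62.6% at 100 FPKM or more and 80.5% below, and it went from 79.6% at 2-fold or more to 88.5% at 4-fold or more.

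The listed genes were spread over all 21 wheat chromosomes. Wheat carries subgenomes A, B and D, each with 7 chromosomes, and the A, B and D copies with the same number form a homoeologous group. The identifiers of 2083 genes name a chromosome: 647 in subgenome A, 768 in B and 668 in D. The share of higher genes was 79.3% in A, 81.3% in B and 81.4% in D, and direction did not differ between subgenomes past the threshold (permutation test across genes, p = 0.547, adjusted p = 0.547 over 6 permutation tests). Homoeologous group 2 held the most listed genes, 484, with 167 on 2A, 169 on 2B and 148 on 2D.

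Direction differed between homoeologous groups (permutation test across genes, p = 0.00631, adjusted p = 0.0126), but not among the fewer genes with a log2(FPKM + 1) ratio of at least 2 in either direction (permutation p = 0.322). The tests over groups treat genes as independent. A, B and D copies of the same gene mostly fall in the same group, so if they change together these p-values are too small. In group 2, 414 genes were higher and 70 lower, a share of 85.5% against 79.2% in the other groups (two-sided Fisher's exact test, adjusted p = 0.0138 over 7 groups). In group 1, 199 were higher and 69 lower, a share of 74.3% against 81.7% elsewhere (Fisher's exact test, adjusted p = 0.0212). The other 5 groups did not pass, with adjusted p from 0.250 to 0.823. The difference over groups rested on these 2, since the permutation p was 0.0707 without group 1 and 0.152 without group 2. Over the 21 single chromosomes direction did not differ past the threshold (permutation test, p = 0.0850, adjusted p = 0.102), among which 1A had the lowest share at 69.9% and 2D the highest at 86.5%, neither past the threshold on its own. Over the 40 chromosome arms named in identifiers, direction differed as a whole (permutation test, adjusted p = 0.0263), with the lowest share, 63.6%, on 1BL and the highest, 90.2%, on 1BS. No single arm passed, the smallest adjusted p being 0.137.

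**Figure D3:**
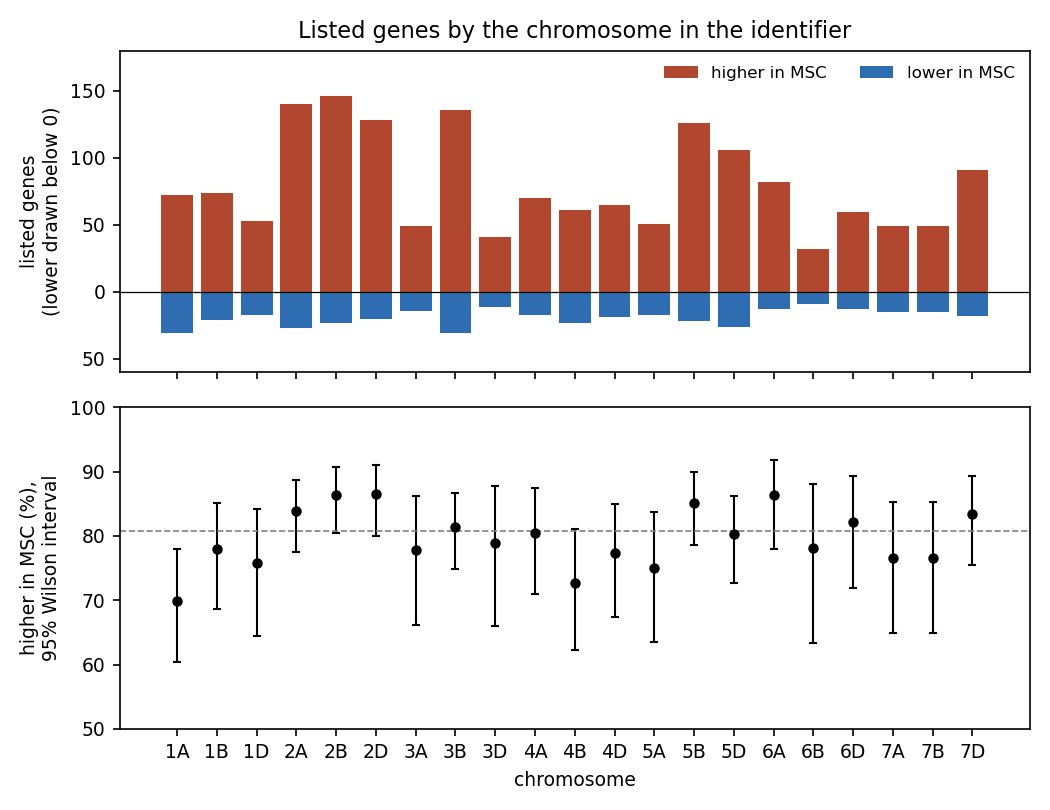
Listed genes by the chromosome in their identifier (x axis): numbers higher and lower in MSC (top, lower genes drawn below 0) and the share higher in MSC (bottom, percent, drawn from 50 to 100, with 95% Wilson intervals and a dashed line at the share over all chromosomes). Chromosomes 2A, 2B and 2D had 140, 146 and 128 higher genes, and 1A had the lowest share at 69.9%.

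The mix of subgenomes among the listed genes differed between homoeologous groups (permutation test across genes, p = 1e-05, the smallest its permutations can give). In group 4 the subgenomes contributed 87, 84 and 84 genes from A, B and D. On the long arms of group 5, 49 listed genes lay on 5AL, 125 on 5BL and 113 on 5DL. In group 6, 95 lay on 6A, 41 on 6B and 73 on 6D, and in group 7, 109 on 7D against 64 on each of 7A and 7B. Chromosome 3B had 167 listed genes against 63 on 3A and 52 on 3D. Of the 3B genes, 142 came from a separate 3B annotation, and without group 3 the permutation p was again 1e-05. The number of annotated genes per chromosome in the authors' annotation was not used here, so these are counts and not rates.

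Assembled loci without a chromosome in their identifier (XLOC numbers) formed 494 of the listed items. They were less abundant, with a median of 2.71 FPKM in the higher group against 6.35 FPKM for the 1941 genes with Traes identifiers. Of them 375 were higher and 119 lower in MSC, a share of 75.9% against 80.7% of all other items (two-sided Fisher's exact test across genes, p = 0.0211, adjusted p = 0.0264). They also held 75 of the 157 items listed at 0.001 FPKM in 1 group.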

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

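Of the alternatives, counting identical copies once, omitting rows out of order and the 4-fold limit were chosen after seeing the data. So were rescaling at 8-fold, the exact test under 0.1 FPKM and all those over homoeologous groups. More genes were higher than lower under the settings run without rescaling. With the groups rescaled to equal upper quartiles, lower genes outnumbered higher ones at 4-fold or more. There 314 genes were higher and 494 lower, 38.9% higher, without genes at 0.001 FPKM. At this shift, unlisted decreases just under 2-fold could only lower that share. The shift comes from the listed genes themselves, so these counts do not show which direction a full data set would favour. At a log2(FPKM + 1) ratio of at least 2 there were 211 higher and 24 lower genes, with at least 1 FPKM in both groups 1134 and 341, with at least 5 FPKM in the higher group 1048 and 279, and at a ratio of at least 4-fold, without genes at 0.001 FPKM, 736 and 96; each of these keeps fewer genes by construction. Identical copies counted once (2014 and 517) and the table without the rows out of order (2038 and 519) stayed within 1.5 times. Rescaling to equal upper quartiles left 845 higher and 522 lower genes at 2-fold or more; in a table chosen by fold, the second count is fixed by construction. At 8-fold or more, where neither count is limited by the 2-fold limit of the table, it moved the share of higher genes from 92.0% to 61.2%. The median log2 ratio of higher genes was 1.12 with a pseudocount of 1 FPKM, 1.62 with 0.1 and 0.62 with 5; that of lower genes was -1.30 with 0.1 and -0.57 with 5. The difference in level between higher and lower genes was -0.19 with the mean of both groups and no longer passed. Taking values under 0.1 FPKM in place of 0.001 raised the genes near 0 to 336 in NM and 53 in MSC, and the exact test by direction, on the 336 higher and 51 lower genes under 0.1 FPKM in their lower group, then passed (p = 0.00012); the cause was not tested. The permutation test of direction over homoeologous groups gave p = 0.322 at a log2(FPKM + 1) ratio of at least 2, where fewer genes are tested, and stayed under 0.05 in its other 3 alternatives; those over subgenomes and chromosomes stayed at 0.05 or above in all 4. No paired analysis was possible because the table has 1 value per treatment. For the same reason the planned fits without 1 replicate, with other tests or at a stricter adjusted p were not run, nor were those on gene lists and homoeologs. Depth is unknown, so low values have no stated precision.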

Other observations

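The tests of the predominance of higher genes, of direction on 3B segments, and of the number and direction of consecutive loci were chosen after the values were seen; those of group 2 with copies counted once or within level bins, and of the difference between ratios of consecutive loci, were set down before their results.

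Higher genes outnumbered lower ones by 2056 to 522. If noise of genes near the detection floor caused the excess of higher genes, the share would lie near 50% among better expressed genes. Among the 917 genes of at least 10 FPKM it was 79.4%, with a 95% interval from 76.7% to 81.9%, which argues against it as the whole cause. The share was 82.2% between 10 and 50 FPKM but 62.6%, with an interval from 53.2% to 71.2%, among the 107 genes of at least 100 FPKM, so the excess was smaller there. One scaling factor between the groups stays open. A log2 shift of 0.90 of all ratios would balance the counts past equal distances, though not at every distance. The upper-quartile shift of -1.06, larger in size, left 314 higher and 494 lower genes at 4-fold or more, and 158 and 100 at 8-fold or more. Whether such a shift exists cannot be told apart from a response, since 0 genes below 2-fold are in the table. A response to fungal signals is the biological explanation the design names; it was not tested, and the bags also differed in the mass and sterilisation of the inoculum.

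Homoeologous group 2 held a larger share of higher genes, with a permutation p of 0.00268 against the rest. Copies of one sequence counted several times would inflate this, but with such copies counted once the p was 0.0032. The expression level of the listed genes would do so too, but with direction permuted within 10 bins of mean level the p was 0.00211. Both results argue against these as the whole cause. Neighbouring or duplicated genes changing together stay open, because the table gives no positions. A, B and D copies of the same gene changing together stay open too, because copies were not matched and the permutations treat genes as independent. So does chance, since group 2 was singled out among 7 groups after its share was seen.

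Neighbouring identifiers were listed together. Of the 494 assembled loci, 19 pairs had consecutive numbers, against 1.85 on average (highest 9) in 10000 random draws of as many numbers from the same range (permutation p = 0.0001, the smallest the draws can give), and 16 of the 19 had the same direction against 12.02 in random pairings (p = 0.0421). The draws took every number in the range as equally likely to be listed. They do not allow for unnamed or expressed loci that lie close together, which would also raise the number of pairs. The median difference between the log2(FPKM + 1) ratios of consecutive loci was 0.214, against 1.04 in random pairings (permutation p = 0.0003), which is consistent with one transcript split into 2 loci, although 0 of the pairs had identical values and neighbouring genes that respond alike would give the same closeness. On chromosome 3B, 26 of 31 pairs of identifiers with the same first 4 digits had one direction, against 21.1 in permutations (p = 0.0611), so a direction shared within a segment was not shown there and is not excluded.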
